A study of Mus musculus with 28 samples.

How the data were processed

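RNA was measured in one hemibrain of each of 28 mice, 7 per group. Per the labels' protocols, RNA was extracted from frozen powder with the Qiagen RNeasy plus kit, and libraries were made with Lexogen's QuantSeq 3' mRNA kit (FWD), which reads short tags near the 3' end of polyadenylated transcripts, with unique molecular identifiers for removing PCR duplicates. One tag is read per molecule, so counts do not scale with transcript length, and parts of a gene upstream of its 3' end are not seen. Per the submitters' processing notes, FastQC 0.11.5, STAR, MultiQC 1.0, R 4.2 and edgeR 3.40.2 were used with genome build GRCm38.p6. The program that counted tags, its strand setting and the annotation release are not given in the sources used here.

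The deposited workbook held a sheet of raw counts per gene, a sheet of normalized CPM and a sheet describing the samples. The deposited counts are rounded to at most 2 significant digits, as were 100% of the 1506428 values that were checked. Values of 100 or more, which the rounding changes by up to 4.76%, made up 5.29% of the values and 79.2% of the counts. Column totals differed from the library totals the authors recorded by at most 0.16%. The normalized CPM sheet is a signal the authors made by dividing counts by the library total times a normalization factor, per the file headers of the sample sheet and the values, so its columns do not share one total. It was used only in alternatives. RNA concentration, library totals and normalization factors came from the sample sheet, whose powder weights were not tested. Gene identifiers, coordinates on GRCm38 and gene types are those of the deposited table, and current symbols were matched for 53620 of its 53801 genes, 181 keeping the symbol of the table.

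Groups came from the genotype and treatment labels, and sex, batch, age and RIN from the labels too. Each batch held 1 to 4 mice of each group, and in batch 4 the 4 DKO saline mice were 16 weeks old and the others 15.5 weeks. Replicate numbers follow the order of the samples and only name them. RIN ran from 8.3 to 9.9. Counts of the 84 pairs of libraries within groups were compared with a chi-square test over genes with 10 to 99 counts in both libraries, which the rounding leaves exact, and all pairs differed by more than sampling noise (ratio of chi-square to degrees of freedom 1.075 to 2.748, highest p 7.6e-06), so none was a repeat of another. Replicates are separate mice.

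The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where the closing parts say otherwise. Genes were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15), which left 11123. edgeR 4.0.16 in R 4.3.3 fitted the deposited counts with TMM normalization and a quasi-likelihood model with group, sex and batch as terms over all 28 mice, and glmQLFTest gave the contrasts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 13.6%. The contrasts were DKO saline against WT saline, DKO AAV against DKO saline, WT AAV against WT saline, DKO AAV against WT saline and the difference of the treatment effects between genotypes. Sex interactions were fitted with a group-by-sex term and batch. CPM values in the text were computed from the deposited counts with TMM factors.

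Named genes are Grn and Tmem106b, the 8 genes with the smallest p that rose and the 8 that fell in a comparison among those called with a mean CPM of at least 5 and a symbol that is not a predicted model, up to 3 members with the smallest p of each gene list, and, for the reversal, the 8 genes with the smallest genotype p. Some genes that this rule names are counted but not described, and one is not reported here. Xist and Ddx3y served as a check of the sex labels. Library content by Prl and Gh, mitochondrial and ribosomal genes was looked at after the values had been seen. The 34 gene lists, drawn from general knowledge of mouse brain cell types, regions and pathways, share some members, such as C4b in the complement and reactive astrocyte lists, Ctsd, Ctsb and Ctsz in the microglial and hydrolase lists, and Gfap in both astrocyte lists. Lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, in one direction. List scores are the mean over members of log2 CPM minus the mean of WT saline.

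For the reversal, the share of genotype-changed genes with the opposite sign under treatment was set beside 20 simulations of treated groups without an effect against the same DKO saline libraries, and beside all 35 ways of giving 4 of the DKO saline libraries to the genotype comparison and the other 3 to the treatment comparison. The overlap of DKO AAV and DKO saline calls against the shared WT saline libraries was set beside 20 simulations and 35 splits of those libraries in the same way, added after the overlap had been seen. The 35 splits of DKO saline were also fitted with regional list scores as covariates, likewise added later. All of these splits were fitted over all 28 mice with common sex and batch terms, so every library still entered those terms. Single measures per library were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over 12 tests. The fitting steps were tested on simulated counts of the 11123 genes, drawn from each gene's mean CPM over all libraries, its dispersion and the effective library sizes, rounded to 2 digits like the deposited counts, with 200 genes changed in each of 3 draws. Genes changed 1.25-fold, 1.5-fold and 2-fold were recovered in 9.5%, 52.7% and 85.9% of cases for DKO saline against WT saline, with 5.8% false calls, in 10.4%, 51.2% and 90.9% for DKO AAV against DKO saline, with 4.1% false calls, and in 10.9%, 43.8% and 79.8% for WT AAV against WT saline, with 5% false calls. In all 3, 0 recovered genes had the wrong direction.

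Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, limma-trend on the deposited CPM, no filter on low counts, a filter of at least 5 CPM in 7 libraries, no sex and batch terms, RIN as a term, fitting only the compared groups, leaving out each library and each batch in turn, and a threshold of 0.01 for genotype calls in the reversal. The 5 CPM filter had been planned as a stricter one, but at this depth it kept 11962 genes, more than the default. Alternatives added after seeing the data were library totals as the scaling, counts restored from both sheets, log2 RNA concentration as a term, and leaving out 3 libraries with a cerebellar or striatal score below -1 or 10 libraries that also included olfactory bulb scores above 0.75 or more than 500 Prl and Gh counts. These thresholds were set after the scores had been seen, with DKO AAV replicate 2 just below the olfactory one at 0.73, and the 10 libraries include 0 of DKO AAV. Restoring used the overlap of the rounding intervals of the 2 sheets, which narrowed the median interval of 79689 values of 100 or more from 5.56% to 1.73% of the value. No sample was left out of the comparisons, and sequence reads were not analysed here.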

Results

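Brain gene expression was measured in 28 mice in 4 groups of 7. Wildtype (WT) mice and double knockout (DKO) mice, which lacked Grn and Tmem106b, each received either saline or AAV(L):bPGRN. Grn encodes progranulin, a secreted protein that is taken up into lysosomes, and Tmem106b encodes a lysosomal membrane protein. The vector was a liver-directed AAV coding for human progranulin fused to 8D3, a single-chain antibody fragment that binds the mouse transferrin receptor, a receptor of the endothelium of brain vessels. It was injected into the tail vein at an age of 6 weeks at 1.3e+13 vector genomes per kg, and the brain was taken 9 to 10 weeks later. One hemibrain per mouse, with the cerebellum and without the olfactory bulb, was powdered, and its polyadenylated RNA was counted by 3' tag sequencing. Each WT group held 4 males and 3 females, each DKO group held 3 males and 4 females, and all 4 processing batches held mice of all 4 groups. Total counts per library ran from 1164637 to 2389815, with medians of 1368072 in WT saline, 1369167 in WT AAV, 1708860 in DKO saline and 1573432 in DKO AAV. Of the 53801 genes in the table, 11123 had enough counts to be tested. Unless stated otherwise, levels are CPM, counts scaled to library size, as mean ± SD over 7 mice, fold changes are log2 values ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

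The disrupted genes were read first, as a check of the labels. Tmem106b (ENSMUSG00000029571, chromosome 6, 13069759 to 13089269, plus strand, GRCm38) stood at 119 ± 23.1 CPM in WT saline and 121 ± 17.5 in WT AAV, against 12.8 ± 4.77 in DKO saline and 9.63 ± 2.18 in DKO AAV. Grn (ENSMUSG00000034708, chromosome 11, 102430315 to 102437048, plus strand) stood at 181 ± 73.9 CPM in WT saline, 175 ± 32.5 in WT AAV, 192 ± 66.7 in DKO saline and 126 ± 27.9 in DKO AAV. The labels do not say which part of Grn was deleted, and 3' tags outside the deleted part check nothing, so the Grn values bear neither on the labels nor on the protein. The neighbour Fam171a2 (ENSMUSG00000034685, chromosome 11, 102436981 to 102447682, minus strand) was counted 64 to 160 times per library in WT mice and 0 to 3 times in DKO mice. The 3' ends of the Grn and Fam171a2 gene models share 68 bases, from 102436981 to 102437048, and whether the counting used the strand is not given in the sources used here, so tags from that stretch cannot be assigned to either gene. Xist was counted 63 to 240 times in the 14 females and 0 to 3 times in the 14 males, and Ddx3y 110 to 250 times in males and 5 to 21 times in females.

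**Figure D1:**
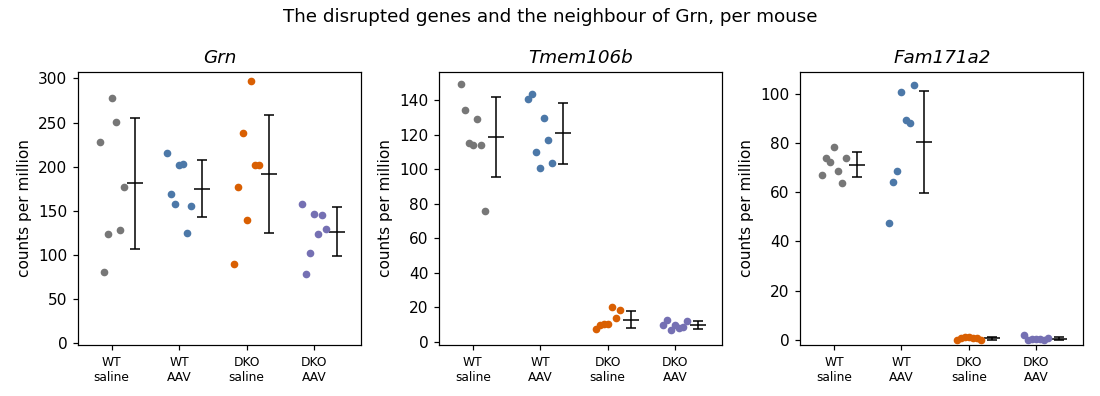
Normalised counts (CPM, linear axes from 0 whose upper ends differ) of Tmem106b, Grn and Fam171a2 in each of the 28 mice, by group, with the group mean ± SD. Tmem106b lay near 120 CPM in both WT groups and near 10 CPM in both DKO groups, Fam171a2 was close to 0 in DKO mice, and Grn tags were present in all groups.

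**Figure D2:**
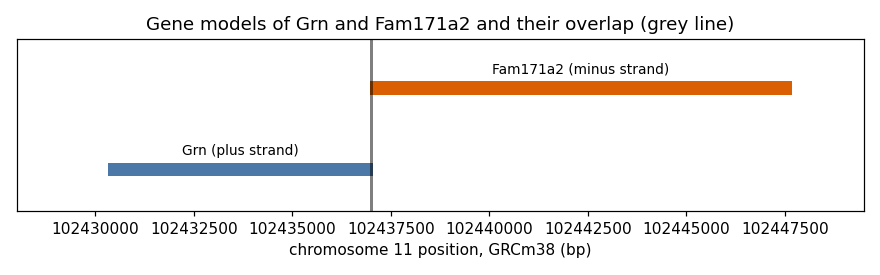
Gene models of Grn and Fam171a2 on chromosome 11 of GRCm38 to scale, in bases, with the strand of each named and a grey line at their overlap. The models run toward each other and their 3' ends overlap by 68 bases.

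Library content differed between mice in ways that accompany the comparisons. Mitochondrially encoded genes took 20.15% ± 0.90 of counts in WT saline and 19.04% ± 1.51 in WT AAV, against 15.82% ± 2.42 in DKO saline and 16.26% ± 2.02 in DKO AAV. The difference between the saline groups gave p = 0.00117 in a two-sided exact permutation test and 0.00702 after Benjamini-Hochberg adjustment over 12 such tests, and DKO AAV against WT saline gave the same values. Region scores, the mean log2 difference of a list's members from WT saline, differed between mice of the same group. The striatal score was -1.42 in DKO saline replicate 2, against -0.14 to 0.12 in the other mice of its group. The cerebellar score was -1.83 in WT saline replicate 6 and -1.37 in WT AAV replicate 7. Olfactory bulb scores above 0.75 occurred in 3 DKO saline, 2 WT saline and 2 WT AAV libraries, more than 500 counts of the pituitary hormone genes Prl and Gh together in DKO saline replicate 3, WT saline replicate 3 and WT AAV replicate 3, and neither in any of the 7 DKO AAV libraries. Both thresholds were set after the values had been seen, and DKO AAV replicate 2 lay just below the first, at 0.73.

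The first comparison asked how loss of both genes changed the brain in saline-treated mice. In DKO brains, transcripts of microglia and astrocytes known from reactive states rose, together with a broad set of lysosomal genes, and mitochondrially encoded transcripts such as mt-Nd1 fell. Tmem106b fell by 3.26 ± 0.17 (adjusted p 2.8e-15) while Grn differed by 0.15 ± 0.19 (adjusted p 0.69). C4b, a complement component (chromosome 17, 34728380 to 34743882, minus strand), rose 8.98-fold, from 8.29 ± 1.53 to 69.5 ± 31.8 CPM (log2 3.17 ± 0.20, adjusted p 1.92e-13). Serpina3n, a protease inhibitor of reactive astrocytes (chromosome 12, 104406729 to 104414329, plus strand), rose 33.6-fold, from 2.31 ± 0.95 to 65.8 ± 59.2 CPM (5.07 ± 0.34, adjusted p 8.13e-13). DKO saline replicate 2 stood at 196.5 CPM, against 19.2 to 63.2 in the other mice of its group. Over the alternatives the log2 change of Serpina3n ran from 4.045 to 5.812. Gfap, the astrocyte intermediate filament (chromosome 11, 102887336 to 102900912, minus strand), rose 4.89-fold, from 96.5 ± 11.2 to 460 ± 287 CPM (2.29 ± 0.18, adjusted p 4.22e-11). C4b has a close paralog, C4a, and Serpina3n lies in a cluster of related genes, so that counting could have split their tags. Clec7a, a microglial pattern receptor, rose by 2.396 ± 0.23, Cd9 by 1.27 ± 0.13, the cathepsin gene Ctsz by 1.29 ± 0.13, the endosomal tetraspanin Cd63 by 0.92 ± 0.10 and the complement initiator C1qa by 1.53 ± 0.18, with adjusted p-values from 1.12e-08 to 4.51e-07. Among the genes that fell, Fam171a2 came first with a fitted log2 change of -6.57 ± 0.26 (adjusted p 9.61e-19), a value that depends on the prior count since 8 counts in all remained in DKO saline. Tags at the mitochondrial genes mt-Tp, mt-Nd6, mt-Te, mt-Ti and mt-Nd1 changed by -1.15 ± 0.13, -0.92 ± 0.12, -1.34 ± 0.19, -1.12 ± 0.17 and -0.65 ± 0.10. Git1, a scaffold protein of synapses, changed by -0.65 ± 0.08 (adjusted p 2.46e-06). All of these genes except Grn differed in the same direction in each of the 4 batches. Over the 12 mitochondrial tRNA genes tested the median was -0.94 (-0.83 with library totals as the scaling) with all 12 called lower, and 7 of the 8 mitochondrial protein genes were called lower. In all, 767 genes changed, 403 higher and 364 lower in DKO, and 2328 had an unadjusted p under 0.05. The count was 361 without the sex and batch terms, 349 when only the compared groups were fitted, 338 with log2 RNA concentration as a term, 455, 243 and 1173 without batch 1, 2 and 4, 410 without DKO saline replicate 2, and 504 without WT saline replicate 1. Scaling by library totals gave 1183 genes, of which 84.5% were higher against 52.5% here, with the median of all genes shifted by 0.12.

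Of the 34 gene lists fixed beforehand, 31 had at least 5 members tested. By limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, 8 ranked higher and 3 lower in DKO saline than in WT saline. Disease-associated microglia genes, markers of a Trem2-dependent state, had the smallest p: 17 of 28 members were higher and none lower (adjusted over the list alone, 22 and 1), with a median of 0.65 and an adjusted p of 1.37e-23. Cst7, a cystatin of that state, rose from 0.52 ± 0.54 to 12.9 ± 6.41 CPM (4.54 ± 0.41). Homeostatic microglia genes also ranked higher, with 8 of 19 risen (8 adjusted over the list alone), among them Trem2 (1.10 ± 0.16), at an adjusted p of 4.3e-06. In the complement list 6 of 11 members rose (8 adjusted over the list alone), including C1qb (1.00 ± 0.13), at an adjusted p of 2.85e-11. Lysosomal hydrolases and their activators had 18 of 44 members higher (23 adjusted over the list alone), such as Ctsd at 1.22 ± 0.15 and Ctsh at 1.36 ± 0.17, at an adjusted p of 2e-18. Lysosomal membrane and acidification genes had 17 of 39 higher and 1 lower (25 and 2 adjusted over the list alone), the one being Tmem106b itself, with Lamp2 at 0.59 ± 0.09 and an adjusted p of 1.8e-13. Reactive astrocyte genes had 7 of 16 higher (10 adjusted over the list alone) at an adjusted p of 2.74e-13. These 6 lists also passed with an estimated correlation, at adjusted p-values of 0.0128, 0.0106, 0.00514, 0.00872, 0.00514 and 0.00514 in the order given. The scores of all 6 were higher in DKO saline than in WT saline within each of the 4 batches, by 0.36 to 1.39 for disease-associated microglia and by 0.59 to 1.27 for reactive astrocytes. The reactive astrocyte score was highest in DKO saline replicate 2, the mouse with the low striatal score, at 1.37 against 0.70 to 0.85 in the rest of its group.

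The other 5 lists that passed with the preset correlation did not with an estimated one. Among genes of MHC class I and antigen processing, 3 of 6 rose (4 adjusted over the list alone), B2m by 0.63 ± 0.11 and H2-K1 by 0.51 ± 0.12, the list at an adjusted p of 0.00065 and at an adjusted p of 0.167 with an estimated correlation. The H2 genes share sequence, and their tags could have been split. The unfolded protein and integrated stress response list ranked higher with 1 of 17 risen (3 adjusted over the list alone), Hspa5 by 0.38 ± 0.08, at an adjusted p of 0.0204, or 0.211 as the adjusted p with an estimated correlation. Synaptic vesicle and postsynapse genes ranked lower with 2 of 33 fallen (2 adjusted over the list alone), Shank1 at -0.51 ± 0.11 and Cplx2 at -0.41 ± 0.13, at an adjusted p of 0.000178, or 0.387 as the adjusted p with an estimated correlation. Excitatory neuron genes ranked lower with 1 of 20 fallen (1 adjusted over the list alone), the upper-layer gene Cux2 at -0.54 ± 0.12, at an adjusted p of 0.0124, or 0.506 as the adjusted p with an estimated correlation. Cholesterol synthesis and uptake genes ranked lower with 2 of 21 fallen (4 adjusted over the list alone), Hmgcs1 at -0.45 ± 0.09 and Srebf2 at -0.33 ± 0.10, at an adjusted p of 0.00725, or 0.211 as the adjusted p with an estimated correlation. Of the genes named here, Srebf2 lost its call in 22 and Cplx2 in 19 of 46 alternatives, both also without DKO saline replicate 2. The excitatory and synaptic scores were lowest in that mouse, whose excitatory score was -1.03 against -0.08 to 0.14 in the other mice of its group.

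Lists that did not pass still held single genes that changed. Of 18 genes of TDP-43 and its binding partners, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with the autophagy receptor Sqstm1 at 0.50 ± 0.08 and the segregase Vcp at 0.37 ± 0.08, and the list gave an adjusted p of 0.978. Astrocyte markers gave an adjusted p of 0.752 with a median of -0.07, a mean of 0.12 and the test pointing upward, 4 of 20 being higher, including the water channel Aqp4 at 0.96 ± 0.14. Myelinating oligodendrocyte genes had 1 higher and 1 lower of 26 (1 and 4 adjusted over the list alone), with Mobp at -0.81 ± 0.14 and an adjusted p of 0.24, the test and the median of 0.01 differing in sign. Neurofilament and axonal injury genes had 2 higher and 1 lower of 12 (adjusted p 0.83), the light chain Nefl at -0.44 ± 0.11. In the heat shock and RNA quality list Bag3 (0.71 ± 0.16) and Hspb1 (1.09 ± 0.27) rose among 12 members at an adjusted p of 0.0891. Type I interferon response genes had 2 of 18 higher, Lgals3bp at 0.86 ± 0.18 and Bst2 at 0.56 ± 0.17, at an adjusted p of 0.169. The endothelial list had 1 of 18 lower, the amino acid transporter Slc7a5 at -0.95 ± 0.20, at an adjusted p of 0.752. In the inhibitory neuron list 1 of 18 was lower, the potassium channel Kcnc1 at -0.51 ± 0.13 (adjusted p 0.694). Blood leukocyte genes had 1 of 6 higher, Trac at 1.13 ± 0.29 (adjusted p 0.169), and immediate early genes had 1 of 16 higher, Jun at 0.44 ± 0.11 (adjusted p 0.386). Thalamic and midbrain genes had 2 of 9 higher (adjusted p 0.628), Ddc at 1.09 ± 0.28 and Th at 1.70 ± 0.48, and Th was also the single member of 6 that rose in the olfactory bulb list (adjusted p 0.752), a tissue whose score exceeded 0.75 in 3 DKO saline and 2 WT saline libraries. No member was called in the lists of oligodendrocyte precursors (adjusted p 0.737), striatal neurons (0.103), cerebellar neurons (0.737), hypothalamic neuropeptides (0.737), transferrin receptor and iron handling (0.433), choroid plexus (0.353), pericytes and vascular fibroblasts (0.795) and red blood cells (0.377). Of the genes named here, Bst2 lost its call in 24 of 46 alternatives, and Bst2, Ddc, Th, Bag3, Hspb1 and Trac lost theirs without DKO saline replicate 2. Adjusted over the list alone, the counts in this paragraph that have no such count beside them were unchanged except for 4 higher and 1 lower in astrocytes, 3 and 2 in neurofilament and axonal injury, and 1 and 1 each in immediate early genes and olfactory bulb. The MHC class II, ependymal cilia and liver lists had 1, 4 and 2 members tested, none of them called, and were too short for the list test.

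**Figure D3:**
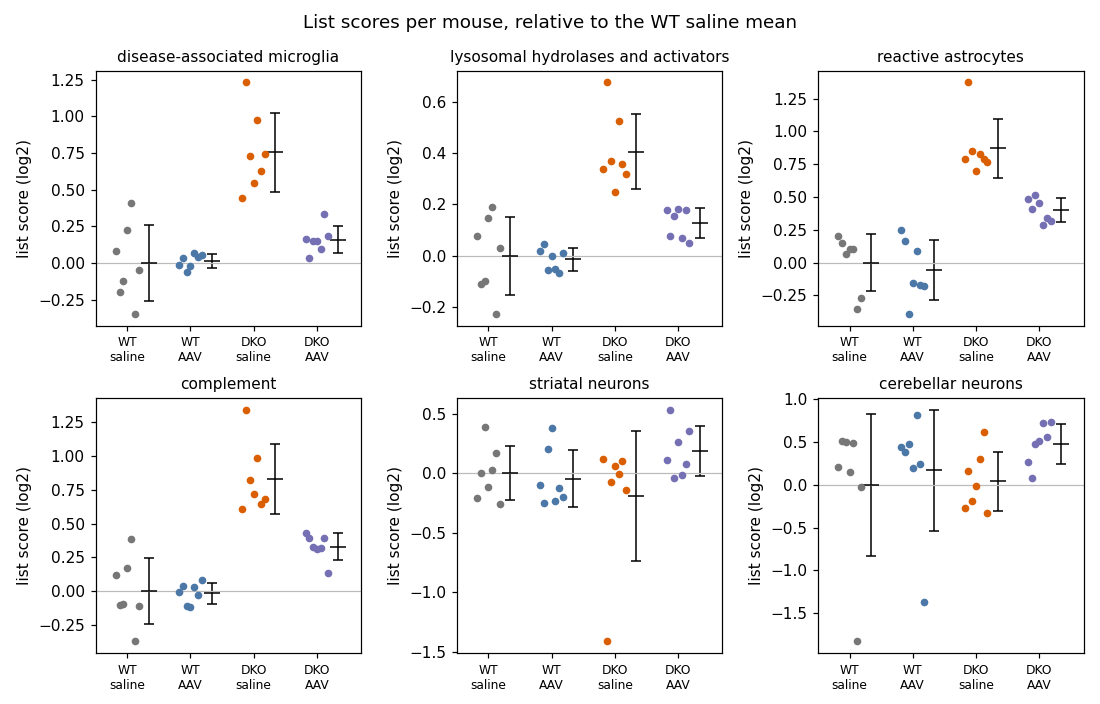
List scores, the mean log2 CPM difference of a list's tested members from the WT saline mean, for each of the 28 mice by group, with the group mean ± SD, in panels for disease-associated microglia, lysosomal hydrolases, reactive astrocytes, complement, striatal neurons and cerebellar neurons. Disease-associated microglia scores averaged 0.76 in DKO saline and 0.16 in DKO AAV, against 0 and 0.02 in the WT groups.

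The comparison of DKO mice with and without the vector asked which of these transcripts differed when the vector was given. In DKO AAV brains the transcripts of reactive microglia and astrocytes, complement and lysosomal hydrolases were lower than in DKO saline brains, and the sodium channel gene Scn1a and the adhesion molecule gene Negr1 were higher. Tmem106b differed by -0.35 ± 0.23 (adjusted p 0.423) and Grn by -0.56 ± 0.18 (adjusted p 0.0802), neither passing the threshold. Serpina3n fell by 1.80 ± 0.22 on the log2 scale, to 20.7 ± 8.36 CPM (adjusted p 8.06e-06). C4b fell by 1.251 ± 0.15, to 31.4 ± 8.02 CPM (adjusted p 8.06e-06), and Gfap by 1.30 ± 0.16, to 190 ± 34.5 CPM (adjusted p 1.35e-05). Ctsz fell by 0.90 ± 0.12, Cd63 by 0.68 ± 0.10, the aspartic protease gene Ctsd by 0.92 ± 0.14, the lysosomal cholesterol carrier Npc2 by 0.65 ± 0.10 and Plek, which encodes the protein kinase C substrate pleckstrin, by 0.70 ± 0.11, with adjusted p-values from 4.42e-05 to 0.000275. Npc2 stood at 353 ± 19 CPM in DKO AAV, against 551 ± 130 in DKO saline and 357 ± 47.1 in WT saline. The genes that rose were led by Tenm1 (0.75 ± 0.15), Ptprr (0.84 ± 0.18), Csmd2 (0.77 ± 0.16), Scn1a (1.15 ± 0.24), Negr1 (0.43 ± 0.09), Zdhhc21 (0.74 ± 0.16), Gpr158 (0.65 ± 0.14) and Dzip3 (0.54 ± 0.12), with adjusted p-values from 0.00685 to 0.011. Scn1a went from 7.92 ± 3.48 to 18.6 ± 4.16 CPM, against 14.8 ± 4.51 in WT saline. Of these 16 genes, 15 kept the direction in all 4 batches and Tenm1 in 3. In all, 336 genes changed, 91 higher and 245 lower, and 2120 had an unadjusted p under 0.05. The number of calls rested on single libraries and batches: it was 54 without DKO saline replicate 2, 700 without DKO saline replicate 1, 77 without the 3 libraries of low cerebellar or striatal score, 13 without the 10 libraries of atypical regional content, 595, 23, 98 and 94 without batch 1, 2, 3 and 4, 204 by limma-trend on the deposited CPM, 710 without a filter on low counts, and 627 when only the compared groups were fitted. Without DKO saline replicate 2 only 5 of the 54 were higher, Negr1, Csmd2, Zdhhc21, Gpr158 and Dzip3 losing their calls, and without batch 2 only 1 of the 23 was. All 8 named genes that rose lost their calls without batch 2 and without the 10 libraries, all but Csmd2 without batch 4, and Scn1a and Ptprr also by DESeq2. Of the 8 named genes that fell, Cd63, Npc2 and Plek lost theirs without the 10 libraries, and the others kept theirs in all alternatives. The count was also 203, 200, 169, 114 and 179 without DKO AAV replicates 2, 3, 4, 5 and 7, 183, 216 and 217 without DKO saline replicates 3, 5 and 7, and 290 with library totals as the scaling, of which 37.9% were higher against 27.1% here.

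With the preset correlation, 10 lists ranked lower and 5 higher in DKO AAV than in DKO saline. Disease-associated microglia genes had 19 of 28 members lower and none higher (24 lower adjusted over the list alone), with a median of -0.59 and an adjusted p of 4.02e-25. The complement list had 4 of 11 lower (8 adjusted over the list alone; adjusted p 1.42e-07), C1qa falling by 0.99 ± 0.17 and C1qb by 0.68 ± 0.12. Among lysosomal hydrolases and activators 12 of 44 were lower (25 adjusted over the list alone; adjusted p 1.63e-12), the cathepsin gene Ctsb falling by 0.59 ± 0.11, and among reactive astrocyte genes 5 of 16 (10 adjusted over the list alone; adjusted p 4.92e-09). These 4 lists also passed with an estimated correlation, at adjusted p-values of 0.03, 0.0312, 0.0423 and 0.03. Their scores were lower in DKO AAV than in DKO saline in all 4 batches, by -0.28 to -1.14 for disease-associated microglia. Homeostatic microglia genes had 5 of 19 lower (9 lower and 1 higher adjusted over the list alone), Trem2 falling by 0.95 ± 0.15 and Aif1 by 0.74 ± 0.17, at an adjusted p of 0.000227, or 0.0517 as the adjusted p with an estimated correlation. Lysosomal membrane and acidification genes had 7 of 39 lower (11 adjusted over the list alone), Cd68 falling by 0.80 ± 0.15, at an adjusted p of 1.66e-06, or 0.0533 as the adjusted p with an estimated correlation. Type I interferon response genes had 2 of 18 lower (5 adjusted over the list alone), Lgals3bp at -0.69 ± 0.16 and Bst2 at -0.67 ± 0.17, at an adjusted p of 3.92e-05, or 0.0533 as the adjusted p with an estimated correlation. MHC class I and antigen processing had 3 of 6 lower (4 adjusted over the list alone), H2-K1 at -0.50 ± 0.12, at an adjusted p of 0.000227, or 0.114 as the adjusted p with an estimated correlation. Astrocyte markers had 3 of 20 lower (4 adjusted over the list alone), with Aldoc at -0.30 ± 0.08, at an adjusted p of 0.00847, or 0.33 as the adjusted p with an estimated correlation. The astrocyte score differed by -0.091, -0.414, 0.008 and -0.015 in batches 1 to 4. Aldoc lost its call in 23 of 46 alternatives, and Aif1, Lgals3bp, Bst2 and H2-K1 also lost theirs without DKO saline replicate 2. Cd68 and Ctsb lost theirs without batch 2 and without the 10 libraries of atypical regional content, and C1qb and Trem2 without those libraries. The log2 change of Cd68 was as small as -0.196 among the alternatives. The unfolded protein and integrated stress response list ranked lower with no member called (4 adjusted over the list alone), at an adjusted p of 0.0125, or 0.167 as the adjusted p with an estimated correlation.

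The 5 lists that ranked higher in DKO AAV were all neuronal, and none passed with an estimated correlation. Synaptic vesicle and postsynapse genes had 1 of 33 higher (10 adjusted over the list alone), the AMPA receptor subunit Gria2 at 0.48 ± 0.13, at an adjusted p of 2.34e-05, or 0.25 as the adjusted p with an estimated correlation. Excitatory neuron genes had none of 20 called (2 adjusted over the list alone) at an adjusted p of 2.44e-05, or 0.138 as the adjusted p with an estimated correlation. Striatal genes had none of 13 called (3 adjusted over the list alone), although all 13 differed upward, at an adjusted p of 0.000324, or 0.306 as the adjusted p with an estimated correlation. Cerebellar genes had none higher and 1 lower of 17 (4 and 1 adjusted over the list alone) at an adjusted p of 0.00733, or 0.589 as the adjusted p with an estimated correlation. Inhibitory neuron genes had 1 of 18 higher (2 adjusted over the list alone), Kcnc1 at 0.48 ± 0.12, at an adjusted p of 0.0172, or 0.306 as the adjusted p with an estimated correlation. Gria2 and Kcnc1 lost their calls without DKO saline replicate 2. The striatal difference between the groups was 1.66 in batch 2, which holds DKO saline replicate 2, and -0.01 to 0.34 in the other 3 batches. Outside these lists, Tia1 of the TDP-43 list rose by 0.75 ± 0.18 (adjusted p 0.0213, not called without that mouse), the list giving 0.124, and the other lists that did not pass lay between there and 0.948. The hypothalamic and pituitary precursor gene Pomc gave -4.52 ± 1.26 (adjusted p 0.0414), with 47 ± 114 CPM in DKO saline and 3.77 ± 2.44 in DKO AAV, and its sign turned to 0.45 without the 10 libraries of atypical regional content, DKO saline replicate 3 with 3490 Prl and Gh counts among them.

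In WT mice no effect of the vector on single genes was detectable. Tmem106b differed by 0.02 ± 0.13 and Grn by 0.01 ± 0.18 between WT AAV and WT saline, both with an adjusted p of 1. C4b stood at 8.29 ± 1.53 CPM in WT saline and 10.7 ± 3.77 in WT AAV, Gfap at 96.5 ± 11.2 and 90.7 ± 11, Ctsd at 474 ± 144 and 511 ± 30.3, and Clec7a at 14.3 ± 7.01 and 16.3 ± 4.55. edgeR called 0 of 11123 genes, DESeq2 0 and limma-voom 0, and 254 genes had an unadjusted p under 0.05 in edgeR, fewer than chance alone would give. Without a filter on low counts 10 genes were called. Simulated data used the library sizes and a spread estimated over all 28 mice, with no sex, batch or regional differences. In them 10.9% of genes given the smallest fold, below 1.5, 43.8% of those changed 1.5-fold and 79.8% of those changed 2-fold were recovered. Smaller effects could thus have been missed, and recovery in the real data can differ. Of the 31 lists camera called 0, the red blood cell list with haemoglobin genes coming nearest at a median of 0.55 (adjusted p 0.0622, or 0.969 as the adjusted p with an estimated correlation), and it called 1 without the sex and batch terms. The disease-associated microglia list had a median of -0.01 (adjusted p 0.86), the transferrin receptor and iron handling list one of -0.05 (adjusted p 0.736), and the type I interferon response list gave an adjusted p of 0.96.

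The interaction asked whether the vector's effect differed between genotypes, which the separate counts for DKO and WT mice cannot show. The genes called were C4b, of complement, and Ctsd, of the lysosome, which lost their calls in 27 and 25 of 45 alternatives. Tmem106b gave -0.37 ± 0.26 (adjusted p 0.618) and Grn -0.57 ± 0.26 (adjusted p 0.397). The effect in DKO minus that in WT was -1.63 ± 0.31 log2 units for C4b and -1.07 ± 0.20 for Ctsd, both with an adjusted p of 0.0441 and the same direction in all 4 batches. These were the 2 calls among 1268 genes with an unadjusted p under 0.05. DESeq2 called 19, limma-voom 0, the fit without the sex and batch terms 0, that with RIN 6, and leaving out single libraries gave 0 to 16, with 24 of the 28 moving the count. Among lists, 11 ranked lower and 3 higher in DKO with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.126. Disease-associated microglia genes had all 28 members with a lower effect in DKO and 1 called (19 adjusted over the list alone), with a median of -0.61 and an adjusted p of 7.39e-20, or 0.126 as the adjusted p with an estimated correlation. Lysosomal hydrolases and activators had 37 of 44 lower and 1 called (10 adjusted over the list alone), at an adjusted p of 2.76e-08, or 0.126 as the adjusted p with an estimated correlation.

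DKO AAV was also compared with WT saline, to describe what was left of the genotype difference. This comparison shares the WT saline mice with the first one and is not independent of it. Tmem106b was lower by -3.61 ± 0.18 (adjusted p 2.1e-16) and Grn differed by -0.41 ± 0.19 (adjusted p 0.216). C4b was still 3.77-fold higher (1.92 ± 0.22, adjusted p 1.05e-06), Serpina3n 9.61-fold (3.27 ± 0.40), Gfap 1.98-fold (0.99 ± 0.18), Clec7a 2.26-fold (1.17 ± 0.25) and Cd9 1.47-fold (0.55 ± 0.13). Cd9 lost its call in 4 of 46 alternatives, among them RIN as a term and leaving out DKO AAV replicate 4. Ctsz, at 52.4 ± 4.40 CPM against 42.1 ± 9.54, no longer passed (0.39 ± 0.14, adjusted p 0.0929). In all, 584 genes differed, 159 higher and 425 lower, and 2140 had an unadjusted p under 0.05. Of the 403 genes raised in DKO saline 59 were still called higher, and of the 364 lowered 171 were still called lower, against 5.76 and 13.9 for independent lists. In 20 simulations with the same WT saline mice and no difference left, 0 to 2 genes were called in DKO AAV at all, too few to show how much overlap the shared mice add. When 4 WT saline mice served the first comparison and the other 3 this one, the medians over 35 splits were 8 and 39 genes, against 0.692 and 1.78 for independent lists. By camera 6 lists ranked higher and 1 lower, and none with an estimated correlation. The higher ones were complement (2 of 11 members higher, adjusted p 0.00553), lysosomal hydrolases and activators (3 of 44, 0.00421), lysosomal membrane and acidification (4 of 39 higher and 1 lower, 0.00418), reactive astrocytes (3 of 16, 0.00421), inhibitory neurons (2 of 18, 0.0118) and cerebellar neurons (1 higher and 1 lower of 17, 0.00672). Adjusted over the list alone, the members higher were 5, 5, 7, 5, 6 and 2. Cholesterol synthesis and uptake genes ranked lower with 3 of 21 lower (5 adjusted over the list alone, adjusted p 0.00421). As adjusted p-values with an estimated correlation the complement, membrane, reactive astrocyte and cholesterol lists gave 0.468, hydrolases and inhibitory neurons 0.591 and cerebellar neurons 0.969. Disease-associated microglia genes, with 3 higher and 1 lower of 28, gave an adjusted p of 0.0805. The number of genes was 319 without the sex and batch terms, 1174 and 1068 without the 3 and the 10 libraries of atypical content, 189 and 226 without batch 2 and 3, 271 without DKO AAV replicate 4, and 355 and 898 without WT saline replicates 1 and 6. With library totals as the scaling it was 1217, of which 83.7% were higher against 27.2% here, the median of all genes being shifted by 0.15.

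Each gene changed by genotype was then followed into the treatment comparison, to see whether it moved back. Of the 8 genes with the smallest genotype p, C4b, Serpina3n, Gfap, Clec7a, Cd9 and Ctsz had risen, and all 6 fell after the vector, Clec7a by 1.22 ± 0.19 and Cd9 by 0.72 ± 0.12. Fam171a2 (-0.16 ± 0.66) and Tmem106b (-0.35 ± 0.23) had fallen, and neither passed the threshold under treatment, Fam171a2 having too few counts to show a change. Of the 767 genes, 646 (84.2%) had the opposite sign under treatment, 149 of them called, and 0 were called in the same direction by edgeR. The 403 raised genes had the opposite sign in 95.5% and 129 were called lower, where independent lists would share 8.88. The 364 lowered genes had the opposite sign in 71.7% and 20 were called higher, where independent lists would share 2.98. Both comparisons use the DKO saline mice, and simulated treated groups without any effect gave 67.3% for raised and 67.6% for lowered genes, with 0.1 calls on average. When 4 DKO saline mice gave the genotype calls and the other 3 the treatment effect, the median over all 35 splits was 86.4% (64.4% to 97.6%) for raised genes and 50.5% for lowered genes. With cerebellar, striatal and olfactory bulb scores as covariates in those splits, it was 75% (43.2% to 95.5%) for raised genes. Without these covariates the splits gave a median of 16 genes called in the opposite direction (0 to 67). They gave 0 to 21 called in the same direction, and 0 to 1 lowered genes called higher. Over all genes the covariance of the genotype and treatment fold changes was -0.047, against -0.016 in the simulations and a median of -0.021 (-0.032 to 0.003) over the 35 splits with no shared library. The simulations called 1536 genotype genes on average against 767 here, so they differed from the data and can understate what sharing adds. Why they called more was not tested. The raised genes had a median log2 change of 0.56 before and 0.24 after treatment relative to WT saline, and the lowered genes -0.49 and -0.38, in genes picked from the same DKO saline mice. The median share of the genotype change moved back was 0.584 for raised and 0.227 for lowered genes, and over the splits with no shared library 0.386 and 0.0019.

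**Figure D4:**
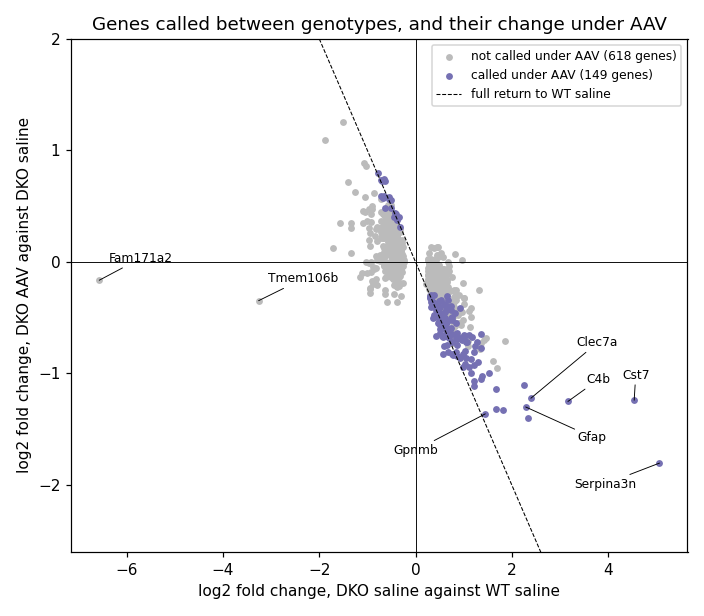
Log2 fold change of the 767 genotype-changed genes, DKO saline against WT saline (horizontal) and DKO AAV against DKO saline (vertical), one point per gene, with the 149 genes called in the opposite direction under treatment in purple, the other 618 in grey, and a dashed line where a gene would return fully to WT saline. Genes raised by genotype lie mostly below 0 on the vertical axis (95.5% of 403) and those lowered mostly above it (71.7% of 364), where simulations without a treatment effect gave 67.3% and 67.6% and the splits with no shared library 86.4% and 50.5%.

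Sex was tested as a modifier of both effects. For the genotype effect edgeR called 0 genes and DESeq2 0, with 892 genes at an unadjusted p under 0.05. The microglial receptor gene Trem2 came nearest, its genotype effect being larger in males by 1.19 ± 0.22 (adjusted p 0.0867). For the treatment effect in DKO mice edgeR called 0 genes and DESeq2 0, with 308 at an unadjusted p under 0.05, and Trem2 had the smallest p, with -0.94 ± 0.25 for males minus females (adjusted p 1). Both tests use the same DKO saline mice, whose males include replicate 2, so the 2 Trem2 values are not independent.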

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

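The tests of DKO saline replicate 2 alone and of regional content, the splits of the strongest gene list, and the bounds for the test of shared DKO saline libraries, whose splits were planned, were chosen only after the result was seen. For single libraries the gap to the nearest mouse of the same group was divided by the range of the group, for 31 list scores and 11 other measures in 4 groups. This picked out 18 of 168 groups, where chance gives about 8.4, or 1 in 20.

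DKO saline replicate 2 accounted for 8 of them. Its ratios were 0.778 for the reactive astrocyte score (1.37, the other mice 0.70 to 0.85), 0.594 for myelinating oligodendrocytes (0.88, the others -0.61 to -0.004), 0.811 for excitatory neurons, 0.831 for striatal neurons, 0.724 for synaptic genes, 0.629 for neurofilament and axonal injury, 0.666 for immediate early genes and 0.695 for Gfap. The cerebellar score stood apart in WT saline replicate 6 (0.769) and WT AAV replicate 7 (0.72), and WT saline replicate 6 also in the interferon score (0.597). DKO AAV replicate 7 stood apart in the complement score (0.589), DKO AAV replicate 3 in astrocytes (0.63) and DKO AAV replicate 6 in thalamic and midbrain neurons (0.581). The others were DKO saline replicate 3 in hypothalamic neuropeptides (0.697), WT saline replicate 5 in heat shock genes (0.594), DKO saline replicate 1 in the choroid plexus score (0.723) and WT saline replicate 7 in Tmem106b (0.603), whose log2 CPM was 6.27 against 6.85 to 7.24 in the rest of its group.

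The treatment effect differed between genotypes for C4b (adjusted p 0.0441) and Ctsd (adjusted p 0.0441) by edgeR's interaction test. By camera with the preset correlation it differed for 14 of 31 lists, and for 0 with an estimated correlation. Lower in DKO were disease-associated microglia (adjusted p 7.39e-20), lysosomal hydrolases and activators (2.76e-08), lysosomal membrane and acidification (1.74e-05), complement (4.08e-05), reactive astrocytes (4.08e-05), type I interferon response (0.000863), MHC class I and antigen processing (0.00793), homeostatic microglia (0.00857), red blood cells (0.0198), unfolded protein and integrated stress response (0.0461) and astrocytes (0.0464). Higher in DKO were striatal neurons (0.00134), excitatory neurons (0.00325) and synaptic genes (0.02). DKO saline replicate 2 has low scores in these neuronal lists.

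Chance could not be excluded for the interaction counts: of 100 splits of the mice, the real one included, 7 gave as many genes (real 2, highest other 126) and 8 as many lists (real 14, highest other 18). A split that called 126 genes may point to a structure of the samples other than the groups, which was not tested. For the strongest of the 31 lists in each split, a test added once the list counts had been seen, 1 of 100 splits reached the real -log10 p of 20.6 (highest other 14.1), which makes chance unlikely for that value. The list concerned, disease-associated microglia, had an adjusted p of 0.126 with an estimated correlation and did not pass there.

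Of the genes raised in DKO saline, 129 were called lower in DKO AAV, with a median treatment change of -0.62 (interquartile range 0.33). Sharing of DKO saline libraries as the only source is argued against by a median of 86.4% of raised genes with a negative change when no library was shared. That share was over 60% in all 35 splits, but these reuse the same mice and are not separate tests. DKO saline replicate 2 alone is argued against by a median of 84.3% over 20 splits, 64.4% to 91.4%. Those splits used it to pick the raised genes and left it out of the treatment groups. All mice entered each fit, so the sex and batch terms still drew on every library, also where none was shared. What this adds was not tested. With cerebellar, striatal and olfactory bulb scores as covariates in the 35 splits the median was 75%, but 43.2% to 95.5% over single splits and above 60% in 28 of them, which is short of the bound set, so regional content may account for part or all of it and cannot be told apart from an effect of the vector. In the 129 genes, which were picked from the same mice, the median was -0.46 without DKO saline replicate 2 and -0.44 with the covariates. The calls ended for all but 36 and 26, with a smaller change and 1 mouse fewer or 3 terms more. Over all genotype-changed genes, 22 of 100 splits of the DKO mice, the real one included, gave an opposite-sign share as large as the real 84.22%. An effect of the vector on the 129 genes remains a hypothesis.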

How the results depend on the processing

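Library totals as the scaling, restored counts, log2 RNA concentration as a term, and leaving out 3 or 10 libraries of atypical regional content were tests chosen only after the result was seen. Counts of calls moved more than single genes did, and where no reason is given the cause was not tested. Of 51 named genes called in DKO saline against WT saline, 27 were never lost under any alternative, and 2160 of 2343 values kept direction and side of the threshold, 183 losing the call. The numbers were 6 of 36 genes and 1431 of 1655 values for DKO AAV against DKO saline, 6 of 7 genes and 318 of 322 values for DKO AAV against WT saline, and 0 of 2 genes and 38 of 90 values for the interaction. The one reversal was Pomc in DKO AAV against DKO saline, at 0.45 without the 10 libraries.

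For DKO saline against WT saline, the 767 genes became 361 without sex and batch terms, 349 with only the compared groups, 1183 with library totals, 338 with RNA concentration and 455, 243 and 1173 without batch 1, 2 and 4. Leaving out single libraries gave 410 (DKO saline replicate 2) to 925 (WT saline replicate 6), and 504 without WT saline replicate 1. For DKO AAV against DKO saline, the 336 became 204 by limma-trend, 710 without a filter, 627 with only the compared groups, 77 and 13 without the 3 and the 10 libraries, and 595, 23, 98 and 94 without batch 1 to 4. Single libraries gave 54 (DKO saline replicate 2) to 700 (DKO saline replicate 1). Removing 10 libraries left 3 DKO saline mice, and fewer samples lower the number of calls by construction, which does not account for the increases. For WT AAV against WT saline, edgeR's 0 genes (254 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0) became 10 without a filter, and single libraries gave 0 to 0.

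For DKO AAV against WT saline, the 584 became 319 without sex and batch terms, 1217 with library totals, 1174 and 1068 without the 3 and the 10 libraries, and 189 and 226 without batch 2 and 3. Single libraries gave 271 (DKO AAV replicate 4) to 898 (WT saline replicate 6), and 355 without WT saline replicate 1. The 2 interaction genes became 19 by DESeq2, 0 by limma-voom, 156 without a filter, 0 without sex and batch terms, 6 with RIN, 5 and 0 without the 3 and the 10 libraries, and 0 without batch 1 and without batch 4. Single libraries gave 0 to 16 (DKO saline replicate 1), with 1268 genes at an unadjusted p under 0.05 in edgeR. The share of genes called higher moved with library totals from 52.5% to 84.5%, 27.1% to 37.9% and 27.2% to 83.7% in the genotype, treatment and DKO AAV against WT saline comparisons. With an estimated correlation the lists went from 11 to 6, 15 to 4 and 14 to 0 for genotype, treatment and interaction, fry gave 5 for the interaction, and WT AAV against WT saline went from 0 to 1 without sex and batch terms. The share of genotype-changed genes with the opposite sign, 84.2%, was 70.9% with no shared library, 81.7% at an adjusted p of 0.01 and 87.5% without sex and batch terms.

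RLE factors, RIN as a term for the genotype and treatment counts, and restored counts moved those counts by less than 1.5 times (genotype 766, 680 and 770, treatment 344, 417 and 323). No paired analysis was possible because replicate numbers only name the samples in their order, and batch is already a term. At 1164637 to 2389815 counts per library, genes given the smallest simulated fold, below 1.5, were recovered in 9.5% to 10.9% of simulated cases. Small effects were thus mostly out of reach at this depth, number of mice and spread, which were not varied separately.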

Other observations

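The tests of a wrong genotype label, of reads shared by overlapping gene ends and of RNA concentration, and the splits of the strongest gene list, were chosen only after the result was seen. Ribosomal protein genes, a family picked after its values were seen, were lower in DKO AAV than in WT saline. Of 80 tested, 48 were called lower, with a median log2 change of -0.33 (-0.20 with library totals as the scaling) and within-batch differences of -0.28, -0.49, -0.43 and -0.07. The lowest RINs of the series, 8.6 and 8.3, were those of DKO AAV replicates 3 and 4, in batches 2 and 3. Whether RIN bears on these genes was not tested. In DKO AAV against DKO saline 12 were lower (median -0.23, or -0.20 with library totals), in DKO saline against WT saline 1 (-0.13, or -0.02), and in WT AAV against WT saline edgeR called 0 (-0.04, or -0.01). The 8 mitochondrial protein genes had 7 lower in DKO saline (median -0.57, or -0.46 with library totals) and 7 lower in DKO AAV (-0.47, or -0.33), both against WT saline, and 0 called between the DKO groups (0.05). Within batches 1 to 4, DKO AAV differed from WT saline by -0.45, -0.75, -0.57 and 0.03.

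Tags counted at mitochondrial tRNA genes were lower in both DKO groups. Of 12 such genes, all were called lower in DKO saline (median -0.94) and 10 in DKO AAV (-1.08, interquartile range 0.16), against WT saline. WT AAV against WT saline gave -0.32 with 0 called by edgeR. The kit reads polyadenylated transcripts and the strand setting is not given, so whether these tags come from the tRNAs themselves was not tested. RNA concentration averaged 19970 ± 11100 pg per ul in DKO saline and 10640 ± 3870 in WT saline (n = 7 each, two-sided exact permutation p 0.0198, adjusted 0.0792 over 12 tests). In DKO AAV it averaged 13890 ± 3690 (p 0.139, adjusted 0.238), and with its log2 value as a covariate the medians were -1.17 in DKO saline and -1.194 in DKO AAV (interquartile range 0.15), with 11 called in the latter, which argues against it as the cause. With log2 library total as a covariate they were -0.63 and -0.724 (0.21), with 8 called in DKO AAV and the latter between the bounds set for and against, so larger libraries in DKO mice could account for part of it and cannot be told apart from the genotype. A genotype effect on these tag counts stays open beside that.

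In DKO mice Grn tags were kept and Fam171a2 tags were lost. A wrong label is argued against, since 0 of 14 DKO libraries reached the lowest WT library in Fam171a2 or Tmem106b. If Grn counts had included the Fam171a2 tags, Grn would have dropped by 71.1 CPM in DKO saline, and it differed by 11 ± 37.6 (SE) CPM there and by -48.9 CPM between DKO AAV and WT AAV, so shared reads cannot be told apart from no sharing at this spread. Genes within 5 Mb of Grn or Tmem106b were called by genotype more often than others, 23 of 158 (14.6%) against 6.77% (two-sided Fisher's exact test p 0.000642). Among them were Gfap (2.29), Stat3 (0.68) and Mapt (-0.46). Only Mdfic and Ica1 of the called genes lay near Tmem106b on chromosome 6, the rest near Grn on chromosome 11, and the loci were not tested apart. An excess near the targeted loci is what strain variants around them would need. Such variants may contribute to these differences, Gfap included, but genes that act together can also lie close together, and an effect of the edit on Fam171a2 itself was not tested.

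Other splits of the mice, 100 for each result with the real one included, made chance unlikely for the number of genes in DKO saline against WT saline (1 as large, real 767, highest other 237), DKO AAV against DKO saline (1, real 336, highest other 320, close to the real count) and DKO AAV against WT saline (1, real 584, highest other 67). For lists, chance was not excluded in DKO saline against WT saline (32 as large, real 11, highest other 16) or DKO AAV against DKO saline (7, real 15, highest other 18), nor was it for the share of genes moving back (22, real 84.22%, highest other 93.71%). Splits compared by the strongest of the 31 lists were added after those list results were seen. They gave 2 of 100 as large for genotype, where 1 other split lay above the real -log10 p (26.3 against 24.4), and 1 of 100 for treatment (25.9, highest other 22.7). Chance is unlikely for both values but not excluded by 100 splits. With a real count of 0, all 100 splits were as large for WT AAV against WT saline, in genes (highest other 41) and lists (highest other 15), and for the sex interactions of genotype (32) and treatment (9). For these edgeR had 254, 892 and 308 genes at an unadjusted p under 0.05, and DESeq2 called 0 in each. Splits calling 41 and 32 genes may point to a structure of the samples beyond the groups, which was not tested.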
